A study of Pseudomonas protegens with 15 samples.

How the data were processed

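Gene expression was measured by RNA sequencing in 15 libraries of Pseudomonas protegens Pf-5, a soil bacterium that lives on plant roots and makes many antibiotics. The libraries formed 5 groups of 3: wild type, a phlAG double mutant without and with 12.5 µg/mL phloroglucinol, and a phlADG triple mutant without and with 12.5 ng/mL phloroglucinol. Per the labels' protocols, cultures were grown at 28 °C with shaking at 200 rpm, in nutrient broth with 1% glycerol, to an optical density of 2.0 to 2.2. Phloroglucinol was dissolved in methanol. Whether the untreated cultures received methanol is not given in the sources used here. RNA was depleted of ribosomal RNA with a capture kit and made into libraries with the TruSeq version 2 kit, per the labels' protocols. No strand setting is given in the sources used here, so reads of overlapping or antisense genes may not be separated.

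The data analysed here are 1 table of fold changes. Per the file headers, each of its 10 columns holds the authors' linear ratio of a pair of groups, with the group named first as the numerator, for 6012 locus tags. The deposited ratios carry 3 decimals, and some cells state that a numerator or denominator was zero together with the other whole number, which ranged from 1 to 26. Between 25 and 52 cells per column were of that kind, and between 354 and 620 read "No data", leaving 5345 to 5624 ratios per column. Genes lacked data in 0, 1, 3, 6 or 10 columns, which are the numbers of pairs that can be formed among up to 5 groups. A group in such a pair can still have ratios to other groups. For phlG, treated phlAG over phlADG read "No data", while wild type over these groups was 786 and 399 in the authors' deposited table. "No data" may thus mark pairs in which both groups had few reads, but no such rule is given. The aligner, the annotation, the counting, the scaling between groups, the pooling of replicates and any test behind the ratios are not given in the sources used here.

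The table has no value per library, no read count per gene apart from the zero cells, and no p-value. The depth of each library is therefore unknown, and the depth behind each ratio is not stated. Some ratios have the form of a whole number divided by a small whole number, such as 399.000 and 278.667 for phlG. Few reads in the denominator group would give such a form. No spread between replicates, standard error, n or test across replicates can be given for any ratio. A gene was counted as higher or lower in a comparison when its deposited ratio differed at least 2-fold from 1. This was the rule set for a table of ratios before the data were examined, when the comparisons, the gene lists and the alternative fold thresholds were also chosen. Count models and linear models that had been planned for values per library were not used.

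An internal check used the fact that all 10 pairs among 5 groups were deposited. For each pair of groups, the ratio can also be rebuilt as the product of ratios through each of the 3 other groups, and these products are called indirect routes below. A gene was called by all routes when the direct ratio and all 3 products differed at least 2-fold from 1 in the same direction. For the 4818 genes with a number in every column, the log2 ratios were fitted by least squares to 5 group levels, leaving 6 residual degrees of freedom. The residual SD had a median of 0.17 on the log2 scale, with 0.04 at the 5th and 0.51 at the 95th percentile. It measures how far the authors' ratios of a gene disagree among themselves, and does not measure the spread between cultures. Every indirect route still holds the libraries of both compared groups, so a chance value of either group enters the direct ratio and all routes alike, and agreement between routes does not exclude it.

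Gene names were not in the table, which holds locus tags only, and no annotation was used. Gene lists were fixed as ranges of locus tags from general knowledge of the published Pf-5 genome: 2,4-diacetylphloroglucinol, pyoluteorin, pyrrolnitrin, hydrogen cyanide, rhizoxin, orfamide, enantio-pyochelin, pyoverdine, the FitD insect toxin and toxoflavin, 10 lists in all. Symbols of phl, plt, hcn and prn genes come from the same knowledge, and the ranges could not be checked against an annotation here. Another 14 lists that needed symbols or product words, such as flagella, ribosomal proteins, efflux pumps and residual stable RNA, were not analysed here. The rule for naming genes took phlA, phlD, phlG, phlF, pltA and pltR, the members of lists with the largest ratios, and the largest ratios outside the lists. The last part was cut from 8 to 1 locus tag per direction, since tags without names say little, and the first tag of 1 run of neighbouring genes was added per direction where a run existed. These runs were chosen after their values were seen. Choice by the largest ratio favours genes with few reads in 1 group. Several tags so named have whole-number ratios, such as 17, 16, 15 and 13, which 1 read in the denominator group would give.

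For each list and comparison, the median log2 ratio was placed among the medians of 10000 random lists of the same size, drawn from all genes with a ratio. These percentiles describe these libraries and are not p-values. As added alternatives, random lists were matched on the residual SD, and the list was placed among all windows of consecutive locus tags of its size. For the pyoluteorin list, counts of genes past 2-fold were also set against 10000 lists drawn gene by gene, matched on residual SD in 10 classes, from the class with the highest residual SD, or from genes lacking some ratio. A planned enrichment test over genes is not given, because the genes of a cluster are not replicates. Runs of at least 4 consecutive locus tags called by all routes were counted and compared with 1000 shufflings of the gene order. Shuffling breaks up operons, whose genes may move together for any reason. An excess over the shufflings therefore does not exclude a chance difference of a group.

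Comparisons that share a group share its chance values. Their correlations and overlaps are therefore given beside 200 simulations in which the 5 fitted group levels of each gene were shuffled among the groups. Each gene was shuffled on its own, so genes of an operon no longer moved together. The ranges over these simulations may thus be too narrow, and a value outside them does not exclude chance. In simulated ratios for phlADG against wild type with the residual SD of the 4818 genes, 193 of 200 genes changed 3-fold passed the 2-fold rule, and 33 unchanged genes passed it. By all routes, 166 of the 200 passed, and 0 unchanged genes did. The simulation gave each ratio its own noise and gave the groups no chance values. It therefore cannot show how often a chance value of a group passes all routes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used. Alternatives were the fold threshold (1.5 and 3), leaving out the phl cluster and, added after the data were seen, division of each column by its median, counting of zero cells against a floor of 3 counts, calls by all routes, and genes with all 10 ratios.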

Results

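The study compared the transcriptomes of Pf-5 wild type and 2 mutants of the phl gene cluster, with and without phloroglucinol, in 15 libraries forming 5 groups of 3. The phl cluster directs synthesis of the antifungal compound 2,4-diacetylphloroglucinol. PhlD makes phloroglucinol, the products of phlA, phlC and phlB acetylate it, and PhlG removes an acetyl group from the end product. By their labels, the phlAG mutant keeps phlD and the phlADG mutant lacks it. The design therefore asks what changes when acetylation is lost, what changes when phloroglucinol synthesis is lost as well, and what added phloroglucinol does to each mutant. All values come from ratios of groups in the authors' deposited table, for 6012 locus tags. Library depths and replicate values are unknown, so the differences below have no replicate check and no p-value.

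The mutated genes were examined first. phlG (PFL_5952) was lower than in wild type by 148-fold in phlAG, 399-fold in phlADG, 786-fold in treated phlAG and 279-fold in treated phlADG, in the authors' deposited table. Treated phlAG over phlADG read "No data" for phlG, and the ratios 399.000, 786.000 and 278.667 have the form that small denominators leave. The sizes of these folds thus probably rest on few reads in the mutants. phlA (PFL_5954) was lower than in wild type by 3.00-fold in phlAG, 2.56-fold in phlADG, 4.0-fold in treated phlAG and 5.86-fold in treated phlADG, in the authors' deposited table. phlD (PFL_5957) was 2.73-fold lower in phlADG and 2.90-fold lower in treated phlADG than in wild type, in the authors' deposited table. Against phlAG, which keeps the gene, phlD was 3.22-fold lower in phlADG and 4.0-fold lower in treated phlADG, in the authors' deposited table. For phlD the authors' deposited table gave ratios of wild type to phlAG of 1.35 without and 1.00 with phloroglucinol. These directions match the genotypes in the labels. Apart from phlG, the size of the drop did not set mutated genes apart. In phlADG, phlF, which the labels do not name as mutated, was 5.0-fold lower than in wild type in the authors' deposited table. Some phlA and phlD signal remained in the mutants, and its source was not tested. Indirect routes for phlA in phlAG gave 3.42- to 6.39-fold, and those for phlD in phlADG gave 2.54- to 4.34-fold.

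**Figure D1:**
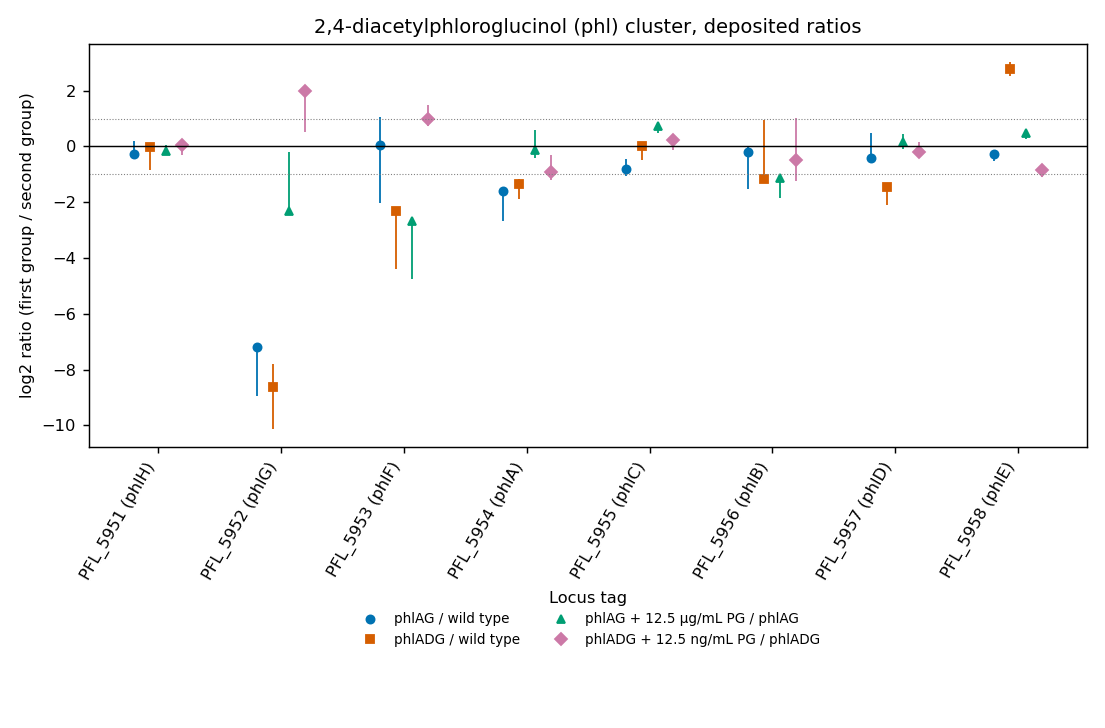
Log2 ratios (y axis, first group over second) of the 8 phl cluster genes (x axis, locus tag and symbol) in 4 comparisons; points are the deposited ratios, vertical lines span the 3 indirect routes where these can be formed, and dotted lines mark 2-fold. phlG lies near -7.21 in phlAG and -8.64 in phlADG against wild type, and phlE lies at 2.77 in phlADG.

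The first comparison set the phlAG mutant against wild type, both without added phloroglucinol. In the authors' deposited table the 3 hydrogen cyanide synthesis genes were higher in the mutant, with a median of 2.10-fold. The authors' deposited table put hcnA (PFL_2577) 3.61-fold, hcnC (PFL_2579) 2.10-fold and hcnB (PFL_2578) 1.58-fold higher, with routes of 1.64- to 3.44-fold for hcnA. All 8 toxoflavin genes, for synthesis and export of a redox-cycling antibiotic, were higher, with a median of 1.84-fold, and 3 of them passed 2-fold. By all routes 1 hydrogen cyanide and 1 toxoflavin gene passed. All 9 genes of the rhizoxin list, for an antimitotic macrolide, were higher with a median of 1.56-fold, and none passed 2-fold. The 4 pyrrolnitrin genes were lower with a median of 1.65-fold, and 1 passed 2-fold, 0 by all routes. Of the 17 pyoluteorin genes, for a chlorinated antibiotic, 16 lay below wild type, with a median log2 ratio of -0.44, and 1 passed 2-fold.

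Within the phl cluster, 2 of 8 genes passed 2-fold in phlAG, the deleted phlG and phlA. The direct ratio of phlF (PFL_5953), which encodes a repressor of the cluster, was 0.964 wild type over phlAG in the authors' deposited table, but its indirect routes ran from 2.07-fold higher to 4.06-fold lower in the mutant. The 3 orfamide genes, for a lipopeptide surfactant, had a median of -0.15 on the log2 scale. The 11 enantio-pyochelin genes had a median of 0.16 and none passed 2-fold. Of 18 pyoverdine genes with a ratio, 2 were lower by 2-fold, 1 after division by the column median and 0 by all routes. Of 7 FitD toxin genes 1 was higher and 1 lower, the latter by all routes. Both siderophore lists serve iron uptake.

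Across the table, 358 of 5553 genes were at least 2-fold higher and 684 at least 2-fold lower in phlAG than in wild type. By all routes, 92 were higher and 194 lower. The median of all genes lay at -0.12, and dividing the column by its median gave 417 higher and 519 lower, so the share of higher genes among those past 2-fold moved from 34.4% to 44.6%. Relative to that shift the list medians were 1.19 for hydrogen cyanide, 1.00 for toxoflavin, 0.76 for rhizoxin, -0.60 for pyrrolnitrin and -0.32 for pyoluteorin, and 0 pyrrolnitrin genes passed 2-fold. The median of the hydrogen cyanide list lay at percentile 99.3 of random lists, that of toxoflavin at 99.96, that of rhizoxin at 99.6, that of pyrrolnitrin at 6.46 and that of pyoluteorin at 4.99. Among windows of neighbouring genes, which may share an operon, the percentiles were 98.3, 98.9, 97.8, 10.04 and 13.1, and among lists matched on residual SD 99.6, 99.99, 99.96, 0.69 and 2.37. Outside the lists, the locus tag with the largest ratio upward was PFL_0491, 14.9-fold higher in the authors' deposited table, whose routes ran from 0.42 to 2.39 on the log2 scale. PFL_1087 had the largest ratio downward, 17 in the authors' deposited table, with no indirect route. Both tags were picked for size, which favours genes with few reads, so these sizes may reflect counting chance. A run of 5 neighbouring genes from PFL_2063 had a median log2 ratio of -3.30, and a run of 6 from PFL_0240 had a median of 1.38.

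The second comparison set the phlADG mutant against wild type. The pyoluteorin list had the largest median of the 10 lists: 16 of its 17 genes were at least 2-fold lower in the mutant, 15 of them by all routes, with a median of 62.5-fold in the authors' deposited table. pltL (PFL_2786), a carrier protein gene, was 291-fold lower in the authors' deposited table, and its routes gave 287- to 517-fold. For pltL, wild type, phlAG and treated phlAG over phlADG read 291.000, 328.500 and 225.000. These have the form that small denominators leave, so the size for pltL probably rests on few reads in phlADG. pltA (PFL_2787), a halogenase gene, was 110-fold lower in the authors' deposited table, and its routes gave 79.7- to 87.8-fold. From pltL to the last gene of the list, 15 genes were lower by 17.7- to 291-fold in the authors' deposited table. pltR (PFL_2785), the LysR-type activator gene of the cluster, was 1.93-fold lower and pltM (PFL_2784), the halogenase gene beside it, 2.01-fold lower in the authors' deposited table. The locus tag that follows the list, singled out after its values were seen, was 8.71-fold lower in the authors' deposited table.

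**Figure D2:**
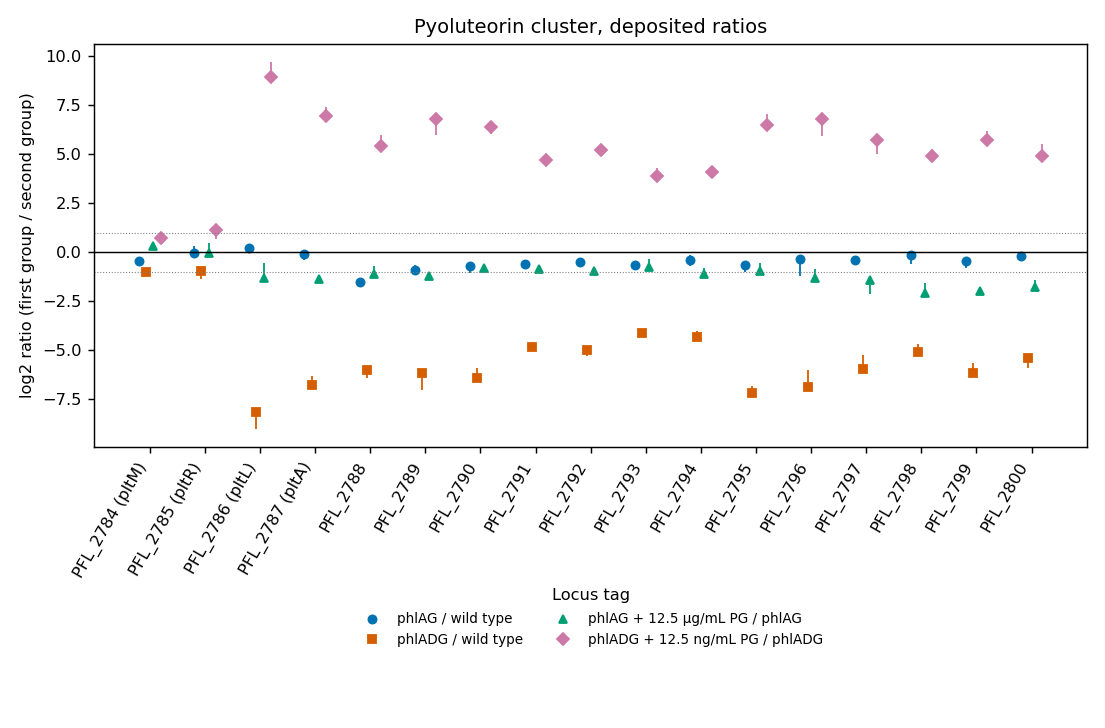
Log2 ratios (y axis, first group over second) of the 17 pyoluteorin genes (x axis, locus tag) in 4 comparisons; points are the deposited ratios, vertical lines span the 3 indirect routes, and dotted lines mark 2-fold. In phlADG the 15 genes from pltL onward lie far below 0 (pltL at -8.18) and with 12.5 ng/mL phloroglucinol they lie far above 0 (pltL at 8.97), while pltM and pltR stay near the dotted lines.

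The hydrogen cyanide genes were all at least 2-fold higher in phlADG than in wild type, with a median of 3.19-fold and a largest value of 3.86-fold for hcnC in the authors' deposited table. Of the 8 toxoflavin genes, 6 passed 2-fold upward, 3 of them by all routes, and the list median was 2.17-fold higher. All 9 rhizoxin genes were higher with a median of 1.74-fold, again with none past 2-fold. Of the 11 enantio-pyochelin genes, 2 passed 2-fold upward and 0 by all routes, with a list median of 1.53-fold. The 4 pyrrolnitrin genes were lower with a median log2 ratio of -0.61, and 1 passed 2-fold, which it did not after division by the column median. In the phl cluster, phlG, phlF, phlA, phlB and phlD were lower by 2-fold or more, and phlE (PFL_5958), an efflux gene beside phlD, was 6.80-fold higher in the authors' deposited table. The routes of phlE gave 5.70- to 8.09-fold, and those of phlF, 5.0-fold lower in the authors' deposited table, gave 6.0- to 20.8-fold. The sizes for phlE and phlF may rest on few reads, which the routes use again. phlB (PFL_5956) was 2.22-fold lower by its direct ratio in the authors' deposited table, but its routes lay on the other side, 1.14- to 1.95-fold higher. Of 19 pyoverdine genes and 3 orfamide genes 0 passed 2-fold, and of 8 FitD toxin genes 2 were higher and 1 lower, 0 by all routes.

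In all, 474 of 5565 genes were at least 2-fold higher and 793 at least 2-fold lower in phlADG. By all routes, 156 were higher and 262 lower. None of the 10000 random lists had a median as low as the pyoluteorin list (percentile 0), and the percentiles were 99.8 for hydrogen cyanide, 99.99 for toxoflavin and 99.8 for rhizoxin. Among windows of neighbouring genes the percentiles of these 4 lists were 0.0721, 99.6, 99.0 and 98.1. Enantio-pyochelin lay at percentile 99.5 of random lists and 96.7 of windows. The phl list, which holds the mutated genes, lay at 0.05 and 2.37. By all routes, 12 runs of at least 4 neighbouring genes were lower, against at most 1 run in 1000 shufflings of the gene order. As the shufflings break up operons, this excess does not exclude a chance difference of either group. The longest run held the 16 genes from pltL to the tag after the list. Another held 5 genes with a median log2 ratio of -3.64 and included PFL_2266, the largest ratio downward outside the lists at 55.3-fold in the authors' deposited table. There were 7 runs of higher genes, the longest of 6 genes from PFL_0240 with a median of 1.72. The largest ratio upward outside the lists was that of PFL_2907, 14.9-fold in the authors' deposited table, with routes from 0.58 to 1.19 on the log2 scale. Its size may reflect few reads.

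The 2 mutants, which differ by the deletion of phlD, were then compared with each other. In phlADG the pyoluteorin genes were lower than in phlAG, with 15 of 17 past 2-fold and a median of 37.0-fold in the authors' deposited table. pltL was 329-fold and pltA 83.3-fold lower, while pltR was 1.85-fold and pltM 1.45-fold lower, in the authors' deposited table. phlF was 10.3-fold lower, with routes of 5.12- to 7.33-fold, and phlE was 9.71-fold higher, in the authors' deposited table. As above, few reads may lie behind these sizes. The hydrogen cyanide genes were 1.74-fold higher at the median and none passed 2-fold. All 8 toxoflavin genes were higher, with a median of 1.58-fold at percentile 99.4 of random lists and 98.9 of windows. Of these, 1 passed 2-fold, and after division by the column median, and by all routes, 0 did. Of 7 FitD toxin genes, 1 was higher by 2-fold. Of the 19 pyoverdine genes, 3 were higher by 2-fold, and none of these was so by all routes. Of 5345 genes, 405 were higher and 397 lower by 2-fold, and 67 and 121 were so by all routes. After division by the column median the split was 327 higher and 411 lower, so the balance of directions depends on the scaling. Outside the lists the largest ratio upward was that of PFL_4378, 14.1-fold, and downward that of PFL_1759, 13-fold in the authors' deposited table. Picked for size, PFL_4378 and PFL_1759 may rest on few reads as well. A run of 4 genes from PFL_2266 was lower with a median log2 ratio of -3.09.

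Adding 12.5 ng/mL phloroglucinol to the phlADG mutant asked whether the compound itself acts on these genes. The pyoluteorin genes were higher in treated than in untreated phlADG, with 16 of 17 past 2-fold and a median of 43.5-fold. In the authors' deposited table the ratio of untreated to treated was 0.002 for pltL, a value of 1 significant digit, and its routes gave 487- to 827-fold. For pltA that ratio was 0.008 in the authors' deposited table, and the routes gave 125- to 172-fold. pltR was 2.17-fold higher, although its routes gave 1.62- to 1.93-fold, and pltM was 1.66-fold higher, in the authors' deposited table. Treated phlADG lay within 2-fold of wild type for these genes: over the 15 genes from pltL onward, wild-type-to-treated ratios ranged from 0.597 to 1.35 in the authors' deposited table, with a median of 1.05. The tag after the list had an untreated-to-treated ratio of 0.105 in the authors' deposited table.

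Of the 8 phl genes, 2 were at least 2-fold higher with the nanogram dose, the residual signal of the deleted phlG at 4.0-fold and phlF at 2.0-fold in the authors' deposited table, and 0 were so by all routes. None of the hydrogen cyanide, toxoflavin, rhizoxin, pyrrolnitrin, orfamide or enantio-pyochelin genes passed 2-fold, and the list medians lay between -0.34 for toxoflavin and 0.37 for pyrrolnitrin. Of the pyoverdine genes, 1 of 19 was lower by 2-fold, and of the FitD toxin genes 1 of 7, neither by all routes. The hydrogen cyanide genes were also above wild type in treated phlADG, with wild-type-to-treated ratios of 0.429 for hcnA, 0.508 for hcnB and 0.337 for hcnC in the authors' deposited table. Of 5393 genes, 448 were higher and 386 lower by 2-fold, and 129 and 64 were so by all routes. Runs of neighbouring genes were seen among the higher genes, 6 in number against at most 1 in the shufflings, and 0 among the lower genes. A run of 5 genes that includes PFL_2266 had a median log2 ratio of 3.06, and PFL_2266 was 41.7-fold higher in the authors' deposited table. The largest ratio downward was that of PFL_0807, 15 in the authors' deposited table, with routes from -1.59 to -1.20 on the log2 scale. Again, choice by size favours genes with few reads.

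The difference of phlADG from wild type was set beside the addition of the compound. That difference covers the loss of phlA, phlD and phlG. Of the 262 genes lower in phlADG than in wild type by all routes, 145 were at least 2-fold higher with 12.5 ng/mL phloroglucinol, and 191 then lay within 2-fold of wild type. Without the pyoluteorin list, the first count was 130 of 247. Of the 156 genes higher in phlADG, 27 were at least 2-fold lower with phloroglucinol and 81 lay within 2-fold of wild type. Both comparisons hold the untreated phlADG libraries, so part of this return may arise by chance. The indirect route through treated phlADG, used to choose the 262 and 156 genes, also holds its ratios to untreated phlADG and to wild type. The choice of genes is thus not separate from the return counted. Nor do these genes show the loss of phlD alone. In phlAG, which keeps phlD, the 262 genes had a median log2 ratio to wild type of -0.96, against -1.67 in phlADG. For the 156 genes the medians were 1.00 in phlAG and 1.42 in phlADG. These medians share the wild-type libraries. Over the 4818 genes with all ratios, 193 were lower against wild type and higher with phloroglucinol by 2-fold. Independent lists would share 32.9, and shuffled groups shared 95.1 on average and 118 at most. That upper bound may be too low, as genes of an operon were shuffled apart. In the other direction, 58 genes were shared against 59.7 with shuffled groups and 18.2 for independent lists. Across genes, which are not independent replicates, Pearson's r was -0.64 and Spearman's rho -0.55, and shuffled groups gave an r of -0.42 on average. The covariance was -0.394 against -0.193 with shuffled groups.

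**Figure D3:**
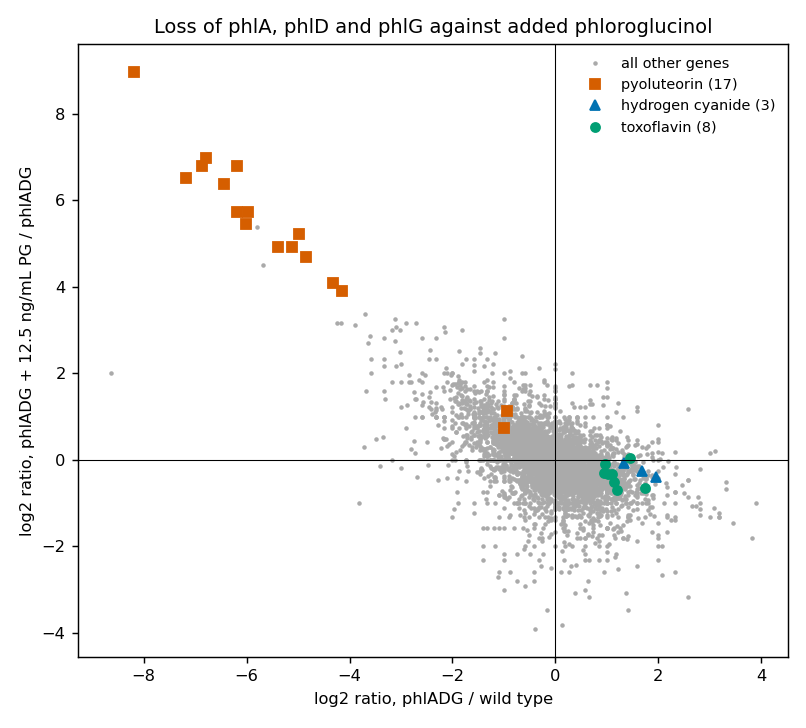
Each point is a gene, with its log2 ratio of phlADG over wild type on the x axis and of phlADG with 12.5 ng/mL phloroglucinol over untreated phlADG on the y axis. Coloured symbols mark the pyoluteorin, hydrogen cyanide and toxoflavin lists; 15 pyoluteorin genes stand at the upper left, and the untreated phlADG libraries enter both axes.

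Adding 12.5 µg/mL phloroglucinol to the phlAG mutant tested a higher dose in cells that keep phlD. Here the pyoluteorin genes were lower with the compound: 10 of 17 passed 2-fold, 6 of them by all routes, with a median of 2.18-fold. In the authors' deposited table pltL was 2.50-fold and pltA 2.60-fold lower, while pltR had a ratio of 1.02 and pltM 0.814, untreated over treated. The routes of pltL gave 1.46- to 2.63-fold. Against wild type, the 15 genes from pltL onward were 2.30- to 6.16-fold lower in treated phlAG, in the authors' deposited table. In the phl cluster, phlF was 6.40-fold lower with routes of 9.17- to 27.0-fold, and phlB 2.20-fold lower, in the authors' deposited table. The size for phlF stays open here too, as few reads may lie behind it. The residual signal of the deleted phlG was 5.0-fold lower in the authors' deposited table, but its routes gave 1.14- to 5.32-fold. The FitD toxin list had a median log2 ratio of 0.61, with 2 of 8 genes higher by 2-fold and 1 of them by all routes. Its medians over the indirect routes were lower, 0.14 to 0.25. Of 18 pyoverdine genes, 2 were higher and 1 lower, with 1 higher and 0 lower by all routes. No gene of the hydrogen cyanide, toxoflavin, rhizoxin, pyrrolnitrin, orfamide or enantio-pyochelin lists passed 2-fold, and their medians lay between -0.14 and 0.30.

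Over all 5396 genes with a ratio, 432 were higher and 308 lower by 2-fold with 12.5 µg/mL, and 88 and 61 were so by all routes. After division by the column median 357 were higher and 321 lower. The share of higher genes among those past 2-fold moved from 58.4% to 52.7%, so the balance depends partly on the scaling. None of the random lists had a median as low as that of pyoluteorin (percentile 0), and pyoluteorin lay at percentile 0.223 of windows of neighbouring genes. The direct FitD median lay at percentile 99.1 of random lists and 97.5 of windows. The only run of neighbouring genes called by all routes was 1 of 4 lower genes inside the pyoluteorin list. The largest ratios outside the lists were those of PFL_3555 and PFL_4378, tied at 13-fold higher, and PFL_2808, 16-fold lower in the authors' deposited table, each with fewer than 3 routes. Chosen for size, these tags too may have few reads in 1 group. The doses and the strains differ together between the additions, 12.5 ng/mL in phlADG and 12.5 µg/mL in phlAG, so neither can be compared alone. Across 4818 genes the log2 ratios of the additions, which share no group, had a Pearson's r of -0.09 and a Spearman's rho of -0.04, against a range of -0.06 to 0.07 for r with shuffled groups. Without the pyoluteorin list r was -0.04, inside that range.

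The differences of both mutants from wild type were also set side by side. Of 4818 genes, 178 were lower by 2-fold in both mutants and 130 higher in both. Independent lists would share 46.4 and 19.0, and shuffled groups, which keep the shared wild type, shared 63.8 and 96.1 on average and 82 and 122 at most. As genes of an operon were shuffled apart, these upper bounds may be too low. Across genes, Pearson's r was 0.53 and Spearman's rho 0.54, against an r of 0.43 on average with shuffled groups, and the covariance was 0.315 against 0.199. For phlAG against wild type and the addition of 12.5 µg/mL to phlAG, r was -0.39 and rho -0.39, against -0.43 on average with shuffled groups, and the covariance was -0.160 against -0.199. Across those, 125 genes were lower in phlAG and higher with phloroglucinol, against 25 for independent lists and 96.5 on average and at most 119 with shuffled groups. In the other direction 29 genes were shared, against 10.2 for independent lists and 61.4 on average with shuffled groups, so this count, r and the covariance were weaker than the averages of shuffled groups, and r lay inside their range of -0.50 to -0.38. Where a count exceeded independent lists, part of the excess may come from the shared group, which cannot be split without values per library.

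**Figure D4:**
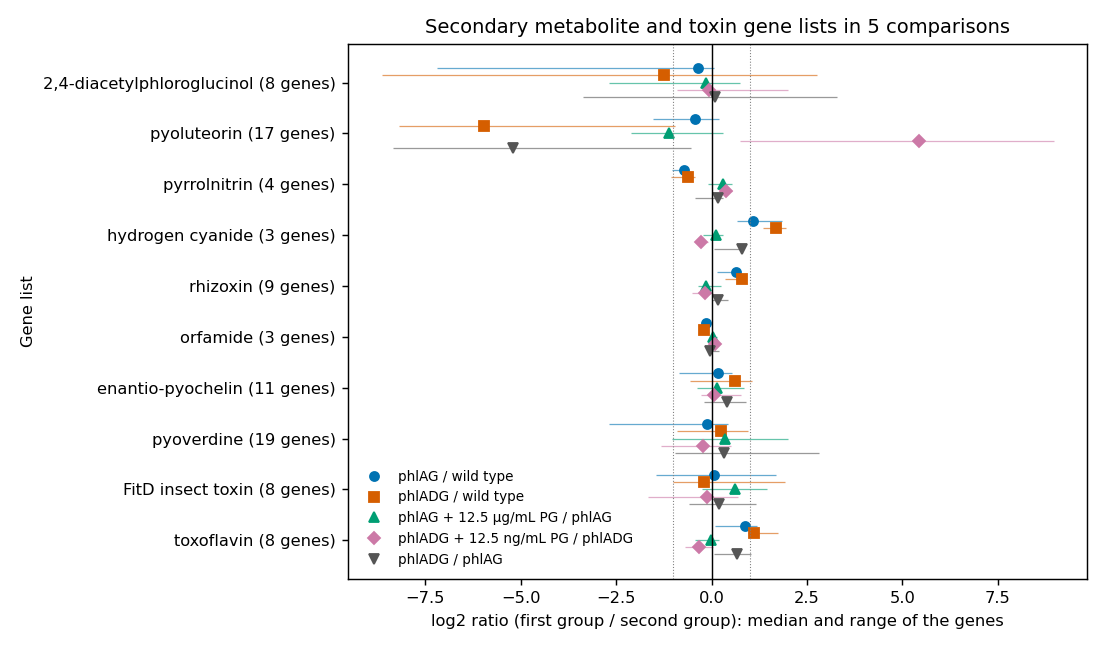
Median log2 ratio (symbols) and range over genes (lines) of 10 gene lists (y axis, with the number of genes) in 5 comparisons, first group over second; dotted lines mark 2-fold. Pyoluteorin stands at -5.97 in phlADG against wild type and at 5.44 with 12.5 ng/mL phloroglucinol, while hydrogen cyanide and toxoflavin lie to the right of 0 in both mutants against wild type.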

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

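Of the tests in this part, those of scaling and of few reads were chosen only after the results were seen, and the counts of genes in which a group stands apart were set before.

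Phloroglucinol went with opposite differences of the pyoluteorin genes in the 2 mutants, at doses given in different units. Of the pyoluteorin genes, 10 of 17 were at least 2-fold lower with 12.5 µg/mL in phlAG and at least 2-fold higher with 12.5 ng/mL in phlADG. Among all 5135 genes with both ratios, 71 showed this pattern and 47 the reverse, against 19.0 and 24.1 for independent lists. Shared directions exceeded independent lists too: of the 4818 genes with all ratios, 39 were higher and 22 lower in both, against 17.7 and 9.77. With shuffled groups these counts averaged 28.5 and 29.0. In the same 4818 genes the pattern held for 46, against at most 40 with shuffled groups, but for 36 without the pyoluteorin list, and the reverse for 28, against 28.7 on average. Beyond the pyoluteorin list, the 36 genes with the pattern thus lay within the range of shuffled groups, above their average of 26.8. These shuffled counts still hold the pyoluteorin genes, and their range may be too narrow because genes of an operon were shuffled apart. A narrower set of genes outside the list is given under other observations. There the count exceeded the most with shuffled groups, where fewer genes qualified. The share lower, 22.9%, lay below the largest with shuffled groups, 32%. The difference between the additions was not tested, since the table holds no replicates, and dose and genotype change together.

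The low pyoluteorin transcripts in phlADG and their higher level with 12.5 ng/mL may have technical or biological sources. A scaling difference between groups is argued against by the median log2 ratio of all genes, -0.068, far from the cluster's -5.97. Counting chance from few reads acts on each gene on its own. Such chance is argued against for the cluster as a set, only as far as disagreement between ratios stands in for depth. Of the 17 genes, 15, all but pltM and pltR, were at least 2-fold lower in phlADG than in all 4 other groups. Among 10000 lists of genes with similar disagreement the count was at most 4, as it was from the 10% of genes with the most. The size of each ratio stays open, as the depth is unknown. A shift of the phlADG cultures or labels also stays open: phlADG lay at least 2-fold from all 4 other groups in 75 genes, 15 of them pyoluteorin genes, fewer than the 139 of wild type, which under the bound set beforehand would count against such a shift. That bound was wrong by design, as the count mixes culture with genotype or phloroglucinol in either group, so the shift cannot be told apart from the loss of phloroglucinol synthesis.

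The higher hydrogen cyanide and toxoflavin genes in both mutants may come from the wild-type libraries they share. Scaling is argued against: after each column was divided by its median, the smallest of the 4 list medians was 1.00 on the log2 scale. Wild type lay at least 2-fold from all 4 other groups in 139 genes, the most of the 5 groups, against 75 for the next. Under the bound set beforehand this would count for a shift of the wild-type cultures or labels. That bound was wrong by design here too, as the count mixes culture with genotype. A difference of the wild-type cultures thus cannot be told apart from an effect of losing phlA and phlG. Of the pattern's genes, 1 hydrogen cyanide gene and 0 toxoflavin genes are among the 139. The table has no values per library, which keeps this open.

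The lower pyoluteorin genes in phlAG with 12.5 µg/mL may likewise have several sources. With the column divided by its median the list median was -1.18, which argues against scaling. Counting chance from few reads was examined for the set too. Of the 17 genes, 10 were at least 2-fold lower, against at most 5 in lists of genes with similar disagreement and at most 8 from the 10% with the most. This argues against such chance only as far as disagreement stands in for depth, as above. Lists of genes that lack some ratio, a class with no pyoluteorin gene, had as many in 7 of 10000 draws. The size of each ratio, methanol, the dose and the cultures stay open, since the depth is unknown and the table has no values per library.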

How the results depend on the processing

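No paired analysis was possible because the table holds ratios of groups and no value per library. So alternatives that need such values (test, normalization of libraries, low-value filter, pseudocount, samples fitted, left-out libraries, p or q threshold, adjustment) were not run. Stable RNA genes and lists by symbol could not be identified without an annotation and were not run, nor was the enrichment test. The 2-fold rule sets the counts. In the order phlAG and phlADG against wild type, 12.5 µg/mL in phlAG, 12.5 ng/mL in phlADG, and phlADG against phlAG, the genes past 2-fold were 1042, 1267, 740, 834 and 802. At 1.5-fold they were 2148, 2367, 1566, 1741 and 1749. At 3-fold they were 398, 483, 252, 303 and 291. By all routes, chosen after seeing the data, they were 286, 418, 149, 193 and 188. With genes that have all 10 ratios the counts were 689 for phlAG against wild type, 469 for 12.5 µg/mL and 554 for 12.5 ng/mL, and the remaining comparisons stayed within 1.5 times. In phlAG against wild type, pyoluteorin genes numbered 5 at 1.5-fold and 0 at 3-fold, hydrogen cyanide genes 1 at 3-fold and 1 by all routes, and toxoflavin genes 5 at 1.5-fold, 0 at 3-fold and 1 by all routes. In phlADG against wild type, phl genes numbered 3 at 3-fold, and toxoflavin genes 1 at 3-fold and 3 by all routes. With 12.5 µg/mL in phlAG, pyoluteorin genes numbered 3 at 3-fold and 6 by all routes. The pyoluteorin counts for phlADG against wild type and against phlAG and for 12.5 ng/mL stayed within 1.5 times at each setting run. Leaving out the phl cluster and counting zero cells moved no count of all genes by over 1.5 times, and the 4 correlations stayed within 0.1 with Spearman's rho, without either cluster and on genes past 2-fold. Counting the smaller lists, 171 values under an alternative stayed in these bounds and 88 left them. The majority direction turned for phlADG against phlAG, from 405 higher and 397 lower to 327 and 411 after division by column medians, 129 and 162 at 3-fold, 67 and 121 by all routes and 270 and 279 with all 10 ratios, and for 12.5 ng/mL, from 448 and 386 to 849 and 892 at 1.5-fold. Fewer genes pass a stricter rule by its construction; no other cause was tested. Column medians, zero cells, all 10 ratios and leaving out pyoluteorin were also chosen after the data were seen. Depth is unknown, which limits every ratio of a weakly expressed gene.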

Other observations

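The values here were computed after the other results had been seen. Pyoluteorin genes were not alone in being low in untreated phlADG. By all routes, 84 genes outside the pyoluteorin list and the tag that follows it were lower in phlADG than in wild type and higher in phlADG with 12.5 ng/mL. These comparisons share the untreated phlADG libraries, which favours such genes by chance: of the 4800 genes with all ratios 83 qualified, against 30.3 on average and at most 45 with shuffled groups. In the phlAG addition, 19 of the 83 were at least 2-fold lower with 12.5 µg/mL, 8 were higher and 56 lay within 2-fold. With shuffled groups, where fewer genes qualified, 3.64 were lower on average and at most 10, and 3.695 were higher on average and at most 9. As shares, 22.9% were lower and 9.64% higher, against 11.9% and 12.1% on average with shuffled groups. The share lower was as large in 10 of 200 shuffles, with 32% at most, so it lay inside their range. The share higher was as large in 128. The routes behind the choice of genes use ratios to both phlAG groups, so the phlAG addition is not fully separate from it. Shuffled groups hold no effect of a treatment and break up operons, so their ranges may be too narrow. Among the 15 pyoluteorin genes chosen in this way, 10 were lower and 0 higher. Of the 4800 genes, 3.65% were lower and 5.90% higher with 12.5 µg/mL. A run of 5 neighbouring genes outside the lists had median log2 ratios of -3.03 in phlADG against wild type, 2.18 with 12.5 ng/mL and -2.10 with 12.5 µg/mL. The table does not name these genes.

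Other runs behaved differently. The 5 genes from PFL_2063 were low in both mutants, with medians of -3.30 and -3.41, and their medians were 0.16 with 12.5 ng/mL and -0.08 with 12.5 µg/mL. The run of 5 that includes PFL_2266 was low in phlADG at -3.64 and high with 12.5 ng/mL at 3.06, yet had a median of 0.28 with 12.5 µg/mL. For phlE, which follows the deleted phlD in locus tag order, the authors' deposited table gave ratios of wild type to mutant of 0.147 in phlADG, 0.316 in treated phlADG and 1.20 in phlAG.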
